A study of Mus musculus with 6 samples.

How the data were processed

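Hippocampus was taken from male C57BL/6N mice, an inbred laboratory strain, aged 8 weeks, per the labels. All 6 libraries are from mice exposed to chronic unpredictable mild stress, a schedule of changing mild stressors used to model depression in rodents. Of these libraries, 3 are from mice given baicalin at 20 mg/kg and 3 from mice given saline. Baicalin is a flavone glucuronide from the root of Scutellaria baicalensis. The labels name an unstressed control group, which is not analysed here, so every comparison is between stressed mice. Nothing in the labels states that each library came from a separate animal, so p-values measure the spread between these libraries. Total RNA was depleted of ribosomal RNA with capture probes and fragmented to between 100 and 300 bp before random-primed library synthesis, per the labels' protocols.

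The deposited table lists 32201 genes, each with a whole-number read count and an FPKM value for every library. The authors' counts are unnormalized, per the file headers and their differing column totals, and the deposited FPKM values are fragments scaled to transcript length and to mapped fragments per library. Per the submitters' processing notes, the tools were bcl2fastq 2.0, HISAT2, StringTie, DESeq2 and limma, and the genome build was mm10; the role and options of each tool are not given in the sources used here. Within a gene, counts and FPKM were proportional once each library had 1 scaling factor, with a standard deviation of the log2 ratio of 0.0011 over 12236 genes with a count of at least 200 and at least 0.5 FPKM in each library. Whether the whole numbers are direct read counts or were derived from StringTie's values is not given in the sources used here. A further 12 per-sample columns match no sample label and were not used here. Of the gene identifiers, 32185 matched GENCODE mouse release 21, and 28973 of these (90.0%) had the same coordinates there; coordinates below are those of the deposited table.

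Library totals ranged from 61303274 to 67957752 counts. The counts of nuclear copies of mitochondrial genes almost equalled those of the genes they copy: Gm28437 had 98.8 to 99.2% of the count of mt-Co3. Reads shared between near-identical genes were therefore probably counted at both, though how reads were assigned is not given in the sources used here. Values of mitochondrial genes and of ribosomal protein genes with processed pseudogenes carry that uncertainty. Whether counting used strand is not given in the sources used here, so genes that overlap on opposite strands cannot be separated.

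The design fixed before the data were examined assumed FPKM alone and limma. Because the table holds counts, edgeR's quasi-likelihood test replaced it, and limma on log2(FPKM + 1) became an alternative. Genes with a mean of at least 1 FPKM over the 6 libraries were kept (13153 genes). Counts were scaled by TMM and fitted with a term for treatment in edgeR 4.0.16 under R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 changes are baicalin minus saline, and the standard error is the size of the log2 change divided by the square root of the F statistic. Levels are TMM-scaled CPM (counts scaled to library size), as mean ± SD over 3 libraries.

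In that design 38 gene lists were fixed, covering stress, synaptic, signalling and metabolic pathways and markers of hippocampal and neighbouring cell types. The 36 lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Each list was tested again with an estimated correlation, with fry and with rank-based camera, and member p-values were also adjusted over the list alone. The genes named were fixed by rule: up to 12 per direction among genes past the threshold whose groups do not overlap, filled by the smallest unadjusted p where fewer passed. Predicted genes without an assigned name were left out. Added to these were up to 4 members with the list's direction and 1 against it for each list past the threshold, up to 3 members of other lists described, and 10 genes always named.

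The procedure was tested on simulated counts drawn from the means and library sizes of these libraries over 13153 genes. It recovered 44.8% of genes changed 1.5-fold, 92.5% changed 2-fold and 100% changed 4-fold, and 12 of its 170 calls were false. More changes were built in than genes passed in the data, which eases the adjusted threshold. These rates may therefore overstate recovery in the data, where Scp2-ps2 (2.52-fold) and Plin4 (3.60-fold) did not pass. A marker list shifted by 0.5 on the log2 scale was called, together with 1 list that had not been shifted. Because genes were simulated independently, this does not test the preset correlation against the correlation between genes in the data.

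Alternatives comprised other filters on mean FPKM (none, 0.1 and 5), other pseudocounts with limma (0.1 and 5), median-of-ratios, quantile and TPM scaling, robust and untrended variance estimates, sample weights through limma voom, counts summed per symbol, a replicate block and the removal of each library in turn. After the data had been seen, limma on log2(FPKM + 1), DESeq2 1.42.0 and the removal of each library's trend with gene length or GC content were added. Length is the summed exon length of a gene, and GC content is that of its longest transcript, both from GENCODE. Figures were drawn with matplotlib.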

Results

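RNA sequencing measured transcript levels in the hippocampus of stressed mice given baicalin (3 libraries) or saline (3 libraries). The comparison asks which hippocampal transcripts differ between stressed mice with and without this compound, which the study's title describes as an antidepressant. Total counts were 61303274 to 64983755 in the baicalin libraries and 65989141 to 67957752 in the saline libraries. Mitochondrial genes took 7.71 to 8.69% of counts with baicalin and 7.18 to 7.82% with saline.

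Few single genes passed the adjusted threshold in edgeR. Gsk3b, which encodes a serine/threonine kinase of the AKT and Wnt pathways, rose 4.50-fold with baicalin, and Setd3, which encodes an actin histidine methyltransferase, rose 1.48-fold. Transcripts that fell were Rbm33, which encodes an RNA-binding protein, and Sh2d5, which encodes a brain-enriched adaptor protein. Also lower were Mief1, which encodes mitochondrial elongation factor 1, and Sel1l, which encodes an adaptor of endoplasmic reticulum-associated degradation. Gsk3b (ENSMUSG00000022812, chromosome 16, 38089001 to 38246084) averaged 166.0 ± 4.41 CPM with baicalin and 36.9 ± 8.87 with saline (SD, n = 3 each). Setd3 averaged 193.6 ± 5.33 against 130.7 ± 6.75 CPM. Sel1l fell from 191 ± 5.80 to 89.1 ± 4.94 CPM, and Rbm33 from 84.9 ± 4.31 to 25.4 ± 3.46.

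**Figure D1:**
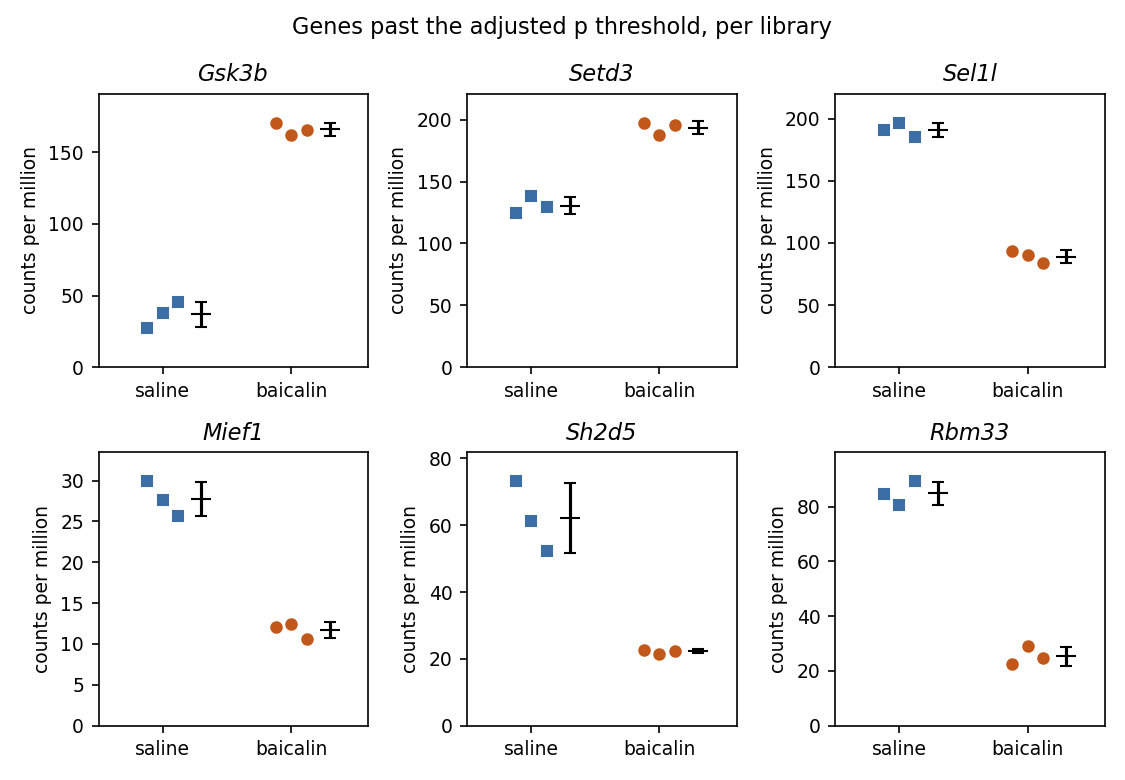
CPM (vertical axes, from 0) of the 6 genes past the adjusted p threshold in 3 saline (squares) and 3 baicalin (circles) libraries; the black line and bar are the mean and SD. In each panel the libraries of the groups do not overlap, as for Gsk3b at means of 36.9 and 166.0.

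By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 of 13153 genes passed the threshold, 2 higher and 4 lower with baicalin. The log2 changes were 2.17 ± 0.17 (SE) for Gsk3b (adjusted p = 0.0227) and 0.57 ± 0.05 for Setd3 (adjusted p = 0.0324) in edgeR. They were -1.74 ± 0.11 for Rbm33 (adjusted p = 0.00906), -1.48 ± 0.12 for Sh2d5 (adjusted p = 0.0260), -1.25 ± 0.10 for Mief1 (adjusted p = 0.0227) and -1.10 ± 0.05 for Sel1l (adjusted p = 0.00409), in edgeR. Sel1l passed in 22 of 23 alternatives and Rbm33 in 20 of 22, against 17 of 23 for Gsk3b, 16 of 23 for Sh2d5, 14 of 22 for Mief1 and 12 of 23 for Setd3. The number of genes called was 0 with a replicate block and 3 with quantile-normalized limma. It was 2 without baicalin library 3, 40 without baicalin library 1, 10 without saline library 2 and 14 without saline library 3. DESeq2 called 211, all 6 of these genes among them. The robust variance estimate called 8 and lost Gsk3b. It newly called Zfp605 (adjusted p = 0.0399 in edgeR), Scp2-ps2 (0.0399) and Raver1 (0.0440). Sel1l alone of the 6 passed without baicalin library 3 (adjusted p of the others from 0.0809 to 0.116 in edgeR). Gsk3b and Sh2d5 also did not pass without baicalin library 2 or saline library 2, Mief1 without these or saline library 1, and Setd3 without baicalin library 2 or saline library 1 or 3. Another split of the 6 libraries parted as many genes by at least 0.5 on the log2 scale as the treatment did (26).

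Of the genes nearest to the threshold, the higher ones included Zfp605 (log2 change 1.10, adjusted p = 0.0523 in edgeR), Scp2-ps2 (1.33), Raver1 (0.93) and Inpp4a (1.11). Kansl2 (0.49), Arhgef2 (0.32) and Sap18 (0.56) were also higher. None of these higher genes was past the threshold in the main fit. Lower ones not past it included Ctnnd2, which encodes delta-catenin (-0.35), Ryr3, a ryanodine receptor calcium channel gene (-0.32), Zfhx2 (-0.37), Zmym1 (-0.46), Smg1 (-0.22), Nin (-0.33), Cdh11 (-0.33) and Tmem64 (-0.33). At an unadjusted p under 0.05 there were 1552 genes, 834 higher and 718 lower, where chance gives 658; under TPM scaling that split was 405 higher and 1432 lower. The groups did not overlap for 2558 genes (19.4%), where chance gives 10%.

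Glucocorticoid-responsive genes were higher with baicalin, as a list fixed in advance (adjusted p = 0.501 with an estimated correlation). Of its 16 members 13 had positive log2 changes, with a median of 0.42. Of all 16, 7 were higher and 1 lower when adjusted over the list alone, against 0 over all genes. The 7 were Plin4, which encodes a lipid droplet protein (log2 change 1.85 ± 0.31, SE), Sult1a1 (0.54), Mt2 (0.52) and Mt1 (0.38), which encode metallothioneins, the transcription factor gene Zbtb16 (0.51 ± 0.07), Pdk4 (0.47) and Ddit4 (0.46). Nr3c1, which encodes the glucocorticoid receptor itself, was the lower one (-0.45 ± 0.08). Fkbp5, which encodes a co-chaperone of that receptor, had 0.55 ± 0.22 (0.32 without saline library 1) and did not pass. The camera test in limma gave adjusted p = 0.00137 with the preset correlation and adjusted p = 0.501 with an estimated correlation. That estimate was 0.13, above the preset 0.01. The list passed in 20 of 20 alternatives with the preset correlation, including each without 1 library, and its median stayed between 0.21 and 0.45.

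**Figure D2:**
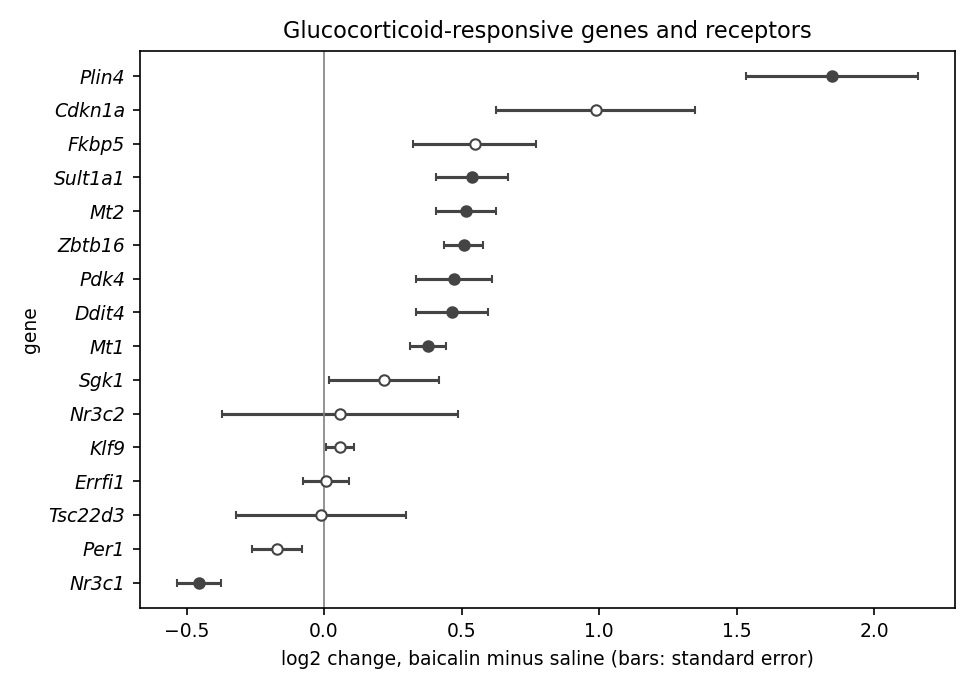
Log2 change, baicalin minus saline (horizontal axis), of each measured member of the glucocorticoid list, with bars for the standard error from 3 against 3 libraries. Filled circles passed when adjusted over the list alone, from Nr3c1 at -0.45 to Plin4 at 1.85; open circles did not.

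The lists of cytosolic ribosomal proteins and nuclear-encoded respiratory chain subunits were slightly higher with baicalin, each with adjusted p = 0.501 with an estimated correlation. Of 59 cytosolic ribosomal protein genes, 57 had positive log2 changes (median 0.18), with 29 higher when adjusted over the list alone and 0 over all genes. Examples were Rps14 (0.28), Rps3 (0.27), Rpl7a (0.25) and Rps15 (0.28), and Rps25 went against it at -0.24. Of 46 nuclear genes for respiratory chain subunits, 42 had positive changes (median 0.18). Of these, 12 were higher when adjusted over the list alone, against 0 over all genes. Cox4i1 had 0.33, Atp5j2 0.22, Ndufa8 0.21 and Cox7a2 0.17, and Atp5d went against it at -0.08. Camera in limma gave adjusted p = 1.21e-17 for the ribosomal list and 9.88e-11 for the respiratory chain list with the preset correlation. The correlations estimated from the data were 0.32 and 0.43, far above the preset 0.01, so these p-values are probably too small. Baicalin library 3 stood apart, with the highest mitochondrial share (8.69%) and a mean over respiratory chain genes of 0.17 relative to all libraries, against 0.08 and -0.008 in the other baicalin libraries. Without it the respiratory chain median was 0.13. Short genes were higher across the transcriptome: with genes in 5 equal bins of exon length, the median log2 change was 0.11 in the shortest bin and -0.07 in the longest, and median lengths were 1830 bp for the ribosomal list and 1508 bp for the respiratory chain list against 4098 bp for all genes tested. With the length trend removed the ribosomal median was 0.11 and the respiratory chain median 0.09, and under TPM scaling they were 0.09 and 0.10, with both lists still past the threshold. The 13 genes of the mitochondrial genome had a median of 0.10, negative with the length trend removed and 0.03 without baicalin library 3, and did not pass (adjusted p = 0.0610 by camera in limma), with mt-Co3 at 0.26, mt-Co2 at 0.25 and mt-Cytb at 0.16. That list passed in 8 of 20 alternatives, among them limma on FPKM, voom with sample weights, the GC trend removed and the fits without baicalin library 2 (adjusted p = 0.00289 by camera in limma) or saline library 3. It also passed by rank-based camera in limma (adjusted p = 0.0413).

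Lists of postsynaptic, GABA receptor, glutamate receptor and immediate early genes were lower with baicalin, each with adjusted p = 0.501 with an estimated correlation. The synaptic vesicle and monoamine lists did not pass (adjusted p = 0.486 and 0.455 by camera in limma). Of 16 postsynaptic scaffold and kinase genes 13 had negative log2 changes (median -0.07), and the scaffold genes Shank3 (-0.25), Homer2 (-0.33), Shank2 (-0.32) and Dlg2 (-0.87) were lower when adjusted over the list alone, with 0 over all genes. Camk2b was at 0.15 (-0.04 without saline library 2). All 14 GABA receptor subunit genes had negative changes (median -0.11), among them Gabrb1 (-0.17), Gabbr2 (-0.10) and Gabrb2 (-0.32), with 0 passing over the list alone or over all genes. The mean over this list in baicalin library 1 (0.02 relative to all libraries) lay within the saline range of -0.03 to 0.10. Among 21 glutamate receptor genes, 13 were negative (median -0.06), including Grm5 (-0.28), Grin2b (-0.18), Grin2a (-0.19) and Gria3 (-0.35), with Grik4 at 0.06 (negative under TPM scaling) and 0 passing over the list alone or over all genes. Immediate early genes, which neurons transcribe in response to activity, had negative changes in 13 of 15 (median -0.33): Egr1 (-0.48), Fos (-0.52), Egr4 (-0.33) and Nr4a1 (-0.43), with Btg2 at 0.33 and 0 passing over the list alone or over all genes. Camera in limma gave adjusted p = 0.00655 for the postsynaptic list, 0.0116 for the GABA receptor and immediate early lists and 0.0485 for the glutamate receptor list, with the preset correlation. Estimated correlations were 0.18 (postsynaptic), 0.16 (GABA receptor) and 0.16 (immediate early), above the preset 0.01, and -0.006 for the glutamate receptor list. Median exon length was 9852 bp in the postsynaptic list. With the length trend removed the postsynaptic (median -0.03 ± 0.08, standard error over members), GABA receptor (-0.07 ± 0.02) and glutamate receptor (-0.02 ± 0.03) lists did not pass. The glutamate receptor list passed in 11 of 20 alternatives. It was also lost with no filter or one of at least 0.1 FPKM, with the GC trend removed and with a replicate block. The immediate early list passed in 17 of 20, and was also lost with at least 5 FPKM. Leaving out 1 library also ended calls by camera in limma: postsynaptic without baicalin library 2 (adjusted p = 0.0690), immediate early without saline library 1 or 2 (up to 0.104), GABA receptor without baicalin library 2 or 3 or saline library 2 (up to 0.0732), and glutamate receptor without baicalin library 3 or any saline library (up to 0.337).

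CA1 pyramidal cell markers were lower as a list (adjusted p = 0.580 with an estimated correlation), with negative changes in 8 of 9 (median -0.24), for example Fibcd1 (-0.35), Man1a (-0.36), Pou3f1 (-0.27) and Nov (-0.24), and Mpped1 at 0.22 (-0.08 without saline library 2). Of these, 0 passed over the list alone or over all genes. Circadian clock genes had negative changes in 14 of 17 (median -0.09), and Per2 (-0.37 ± 0.07, SE) was lower when adjusted over the list alone, with 0 over all genes. Arntl was at -0.27, Bhlhe40 at -0.14, Nr1d1 at -0.12 and Ciart at 0.23. Camera in limma gave adjusted p = 0.0138 for CA1 markers and 0.0165 for clock genes (adjusted p = 0.501 with an estimated correlation). The estimated correlation was 0.33 for CA1 markers, above the preset 0.01, and -0.006 for clock genes. The mean over CA1 markers was lowest in baicalin library 2 (-0.26 relative to all libraries), while baicalin library 1 (0.04) lay within the saline range of 0.03 to 0.15. The clock list did not pass with the length trend removed (median -0.07 ± 0.04, standard error over members) or without baicalin library 2 or 3 or saline library 3 (up to adjusted p = 0.0696 without a library, by camera in limma), though its median was -0.06 or lower in all 20 alternatives. The CA1 list did not pass without baicalin library 2 (adjusted p = 0.108 by camera in limma), and its median was -0.15 without saline library 2.

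**Figure D3:**
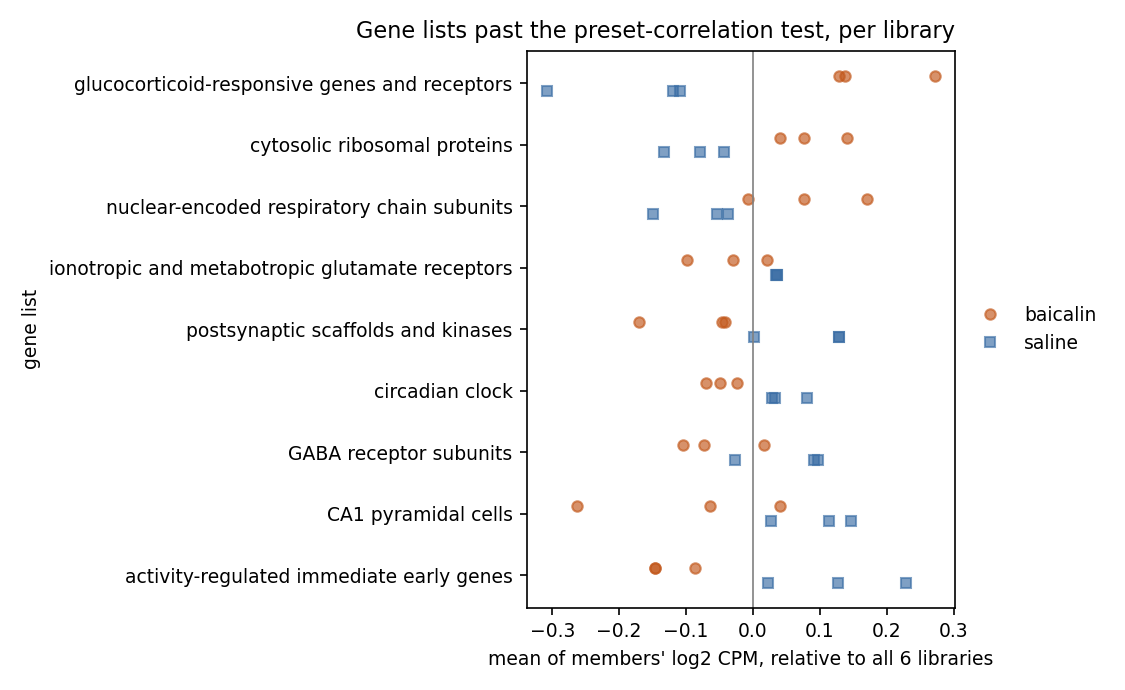
Mean over list members of log2 CPM relative to the mean of all 6 libraries (horizontal axis), 1 point per library, for the 9 lists past the camera test with the preset correlation; circles are baicalin and squares saline, and points can cover each other. The baicalin libraries lie between 0.13 and 0.27 for the glucocorticoid list, and the saline libraries between -0.31 and -0.11.

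Other cell type markers showed no list past the threshold in the main test. Median log2 changes were 0.18 for dentate granule cells (Tdo2 0.40), 0.05 for CA2 and CA3 pyramidal cells (Pcp4 0.40, which passed when adjusted over the list alone and not over all genes), -0.07 for interneurons (Dlx1 0.39; median -0.02 without saline library 2), 0.01 for astrocytes (Gjb6 0.32), 0.03 for microglia (C1qb 0.16), -0.0008 for oligodendrocytes (Ugt8a -0.40), 0.02 for their precursors (Sox10 -0.29, and -0.11 without saline library 2), 0.04 for endothelium (Slc2a1 0.42), -0.04 for mural cells (Pdgfrb -0.15) and 0.04 for ependyma (Meig1 0.38); under TPM scaling those for CA2 and CA3 pyramidal cells, astrocytes, microglia, oligodendrocyte precursors, endothelium and ependyma were negative, as was that for astrocytes under quantile scaling. Leaving out 1 library turned the sign of each of these medians except those of dentate granule cells and interneurons, as far as -0.21 for ependyma without baicalin library 2 and -0.11 for endothelium without saline library 2. The dentate granule list passed in 6 of 20 alternatives, among them TPM scaling, voom with sample weights, the length trend removed and the fits without saline library 3 (adjusted p = 0.00663 by camera in limma) or saline library 1. It also passed by rank-based camera in limma (adjusted p = 0.0488). Its median was 0.06 without saline library 2, where the mean over its markers was -0.44 relative to all libraries. Markers of tissue around the hippocampus had medians of 0.32 for thalamus (Ramp3 0.41; median 0.14 without baicalin library 2), -0.19 for striatum (Tac1 -0.22; median -0.10 without baicalin library 2) and 0.03 for cortex (Rprm 0.40; median negative under TPM scaling and without baicalin library 2 or saline library 1). For meninges the median was -0.34 (Dcn -0.46), and 0.30 (Dcn -0.18) without saline library 3, where the mean over the markers was 1.20 against -0.53 to -0.42 in the other saline libraries. Blood and choroid plexus had 4 measured members each, too few to test, with medians of 0.01 and 0.02; Ttr of the choroid plexus was at 0.88 ± 0.73 (SE), and at -0.03 without baicalin library 2.

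Pathways tied to depression and to this compound also did not pass as lists in the main fit. Among PI3K, AKT and FOXO genes (median -0.02) Gsk3b alone passed, over the list alone and over all genes, while Akt1 was at -0.01 ± 0.05 (SE). The neurotrophin list (median -0.09; it passed with a filter of at least 5 FPKM, adjusted p = 0.0200 by camera in limma) held Bdnf at -0.18 ± 0.12 (-0.09 without baicalin library 2), Fgfr1 at -0.18 and Vgf at -0.66 ± 0.27 (-0.25 without saline library 3). The median was 0.05 for inflammation (Nfkb1 -0.22) and negative under TPM scaling. Nlrp3 and Il1b lay below the expression filter at means of 0.161 and 0.0310 FPKM. For adult neurogenesis genes the median was -0.07 (Prom1 0.37, Nes -0.37). Dcx lay below the filter at 0.969 FPKM. Medians were -0.10 for Wnt (Fzd3 -0.19), -0.05 for monoamine genes (Htr1b -0.45), -0.02 for synaptic vesicle genes (Unc13a -0.15; the list passed under quantile scaling, adjusted p = 0.00293 by camera in limma), 0.04 for NRF2 targets (Sod1 0.18), 0.04 for apoptosis (Bid 0.21), -0.04 for heat shock and endoplasmic reticulum stress (Xbp1 -0.14), -0.08 for interferon (Ifitm3 -0.27; the list passed without saline library 1, adjusted p = 0.0102 by camera in limma, and without saline library 3 its median was -0.02 and Ifitm3 -0.01) and -0.01 for stress peptides (Npy 0.13); those for NRF2 targets and apoptosis were negative under TPM scaling. Leaving out 1 library turned the sign of the medians for inflammation, adult neurogenesis, monoamine, synaptic vesicle, apoptosis, heat shock and stress peptide genes, to at most 0.06 in size (stress peptides without saline library 1). By camera in limma the adjusted p of the lists that did not pass ranged upward from 0.0610. Means and medians differed in sign for interneurons, inflammation, adult neurogenesis, PI3K and AKT genes, oligodendrocyte precursors and stress peptides.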

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

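Of 3441 values of named genes under alternatives, 3358 stayed on their side of the threshold, 35 no longer passed and 48 newly passed; of 710 list values the numbers were 670, 23 and 17. Only the 6 genes and 9 lists past the threshold in the main fit could lose a call, so all 35 and 23 losses fell on them. Most other values belong to genes and lists that did not pass, so these totals do not measure how stable the calls are. A sign changed in 26 gene values and 49 list values, each past neither threshold. Leaving out 1 library brought named genes past neither threshold to values over 1.5 times smaller: Tdo2 (0.25), Btg2 (0.21), Man1a (-0.21), Pou3f1 (-0.15) and Nov (-0.15) without saline library 2, Nfkb1 (-0.13) and Bid (0.12) without saline library 3, Rps25 (-0.15) without saline library 1, Gria3 (-0.22) without baicalin library 1, Grik4 (0.02) without baicalin library 2, and Gabrb2 (-0.20), Pdgfrb (-0.05), mt-Co2 (0.16) and mt-Cytb (0.09) without baicalin library 3. The glucocorticoid, ribosomal protein and respiratory chain lists passed with the preset correlation in 20 of 20 alternatives. The preset 0.01 lies below their estimated correlations of 0.13, 0.32 and 0.43. Genes called numbered 3 with quantile-normalized limma, 211 with DESeq2 (128 higher, 83 lower; added after the data were seen) and 2 to 40 with 1 library left out: 2 without baicalin library 3, 40 without baicalin library 1, 10 without saline library 2 and 14 without saline library 3. Of the 6 genes, 3 were shared with the quantile fit and 1 with the fit without baicalin library 3. Genes at an unadjusted p under 0.05 numbered 1033 with at least 5 FPKM, where 7118 genes were tested, and 982 to 1653 with 1 library left out, the lowest without baicalin library 3. Lists called numbered 0 with an estimated correlation, 0 with fry, where the smallest p was 0.00694, and 6 to 9 with 1 library left out. Rank-based camera, with the preset correlation, called 11, the mitochondrial genome and dentate granule lists among them. With the length trend removed, 6 lists passed, 5 of them among the 9. The cause of these shifts was not tested. Replicate numbers are shared between the groups, and the labels do not say whether they pair the libraries. The deviations of same-numbered libraries correlated at 0.123, 0.0795 and 0.0124, against -0.102 to 0.0357 for differently numbered ones. Baicalin libraries 1 and 2 correlated best with the saline library of their own number, and baicalin library 3 with saline library 2 (0.0357). These values leave a pairing open, and the main fit did not use one. A replicate block gave 0 genes past the threshold (smallest adjusted p = 0.0889 in edgeR) and 1120 genes at an unadjusted p under 0.05. With that block 10 lists passed, and the glutamate receptor list did not. At the depth of 61303274 to 67957752 counts, 44.8% of simulated 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes were recovered. Those rates may overstate recovery in the data, where fewer genes passed than in the simulation.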

Other observations

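KEGG pathways of the deposited annotation, tested after the data had been seen, extended the list results to other machinery. Among 262 pathways of 15 to 300 genes, 8 were higher and 12 lower by camera in limma with the preset correlation. The higher ones included oxidative phosphorylation and the Parkinson's, Alzheimer's and Huntington's disease pathways. Pathways can share genes with each other and with the lists above, so their number does not count separate signals. With an estimated correlation 0 pathways passed (smallest adjusted p = 0.526 by camera in limma). Proteasome genes were higher (41 genes, median log2 change 0.09, adjusted p = 0.000114; adjusted p = 0.526 with an estimated correlation), as were spliceosome genes (122 genes, median 0.05, adjusted p = 0.0149; adjusted p = 0.610 with an estimated correlation) and ribosome genes (129 genes, median 0.13; adjusted p = 0.526 with an estimated correlation). Glutamatergic synapse genes were lower (93 genes, median -0.07, adjusted p = 0.00289), with axon guidance (145 genes, median -0.06) and MAPK signalling genes (189 genes, median -0.04), each with adjusted p = 0.526 with an estimated correlation. With the length trend removed 5 pathways passed: the higher ribosome, proteasome, spliceosome and Parkinson's disease pathways, and the lower neuroactive ligand-receptor interaction (adjusted p = 0.0423 by camera in limma). The glutamatergic synapse (adjusted p = 0.480), axon guidance (0.932), MAPK signalling (0.729) and oxidative phosphorylation (0.0515) did not, by camera in limma.

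Genes outside the naming rule, chosen after their values were seen, included Hif3a (log2 change 1.03), Xdh (0.86), Mfsd2a (0.57), Htra1 (0.37), Sdc4 (0.32) and Glul (0.27), each higher with baicalin and none past the threshold in edgeR.

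Of the tests that follow, those on low counts, on the share of endothelial cells or astrocytes, on whole causes by list scores, and on splits for unadjusted p and for KEGG pathways were chosen after the result was seen. The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. Along the treatment 6 genes passed, against 10 at most along another split, and 5 of the 10 splits gave as many. For gene lists it was 9 against 9, with 3 splits giving as many. At an unadjusted p under 0.05 the treatment gave 1552 genes and the highest other split 874, and for KEGG pathways 20 against 5, with 1 split, the treatment's own, as large in each.

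The first pattern is the abrupt change of single genes such as Gsk3b and Rbm33. Low counts are argued against, since the median over the 6 genes of the mean count per library was 5021. Steps in a gene's counts that strike libraries regardless of group may account for some of these genes: 26 genes had their groups parted by at least 0.5 on the log2 scale along the treatment, and 26 along the highest of the 9 other splits. Of 10821 genes with a mean count of at least 500, 393 (3.63%) had a library over 2-fold from the median. An effect of baicalin on these genes stays open alongside it.

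The second pattern is the higher level of ribosomal protein and respiratory chain genes. For the ribosomal list the median log2 change was 0.16 with the GC trend removed and at least 0.15 without any baicalin library. Both lie above the 0.12 set in advance by more than the standard error over members. That error takes members as independent, though their estimated correlation was 0.32, so a part played by either stays open. As the whole cause 1 baicalin library is argued against. With any 1 of them left out the groups' mean list scores differed by at least 0.14 (SD between libraries 0.04), over 2 times that SD each time. A trend with GC content was not tested by list scores and stays open, though its removal lowered the median only from 0.18 to 0.16. A trend with summed exon length as the whole cause is also argued against for the ribosomal list. With that trend removed the groups' mean list scores still differed by 0.10, over 2 times the SD between libraries (0.03). The same cause stays open for the respiratory chain list (difference 0.0780, SD 0.0452). Summed exon length can exceed the length of the transcripts expressed, so a trend with the latter stays open for both lists. A trend with gene length could account for part of both. The ribosomal median went from 0.18 to 0.11 ± 0.02 (standard error of the median over members), short of the 0.12 set in advance. The respiratory chain median went from 0.18 to 0.09, while both lists still passed. An effect of baicalin stays open, RNA integrity was not measured here, and the length trends of the groups did not overlap: slopes per doubling of length were -0.06, -0.02 and 0.009 with baicalin, against 0.015, 0.02 and 0.03 with saline.

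The third pattern is the higher level of glucocorticoid-responsive genes. A larger share of endothelial cells or astrocytes as its whole cause is argued against, but only weakly. The higher of their marker medians (0.04) lies 0.39 below the list's median of 0.42. That is more than the combined spread of 0.28 (SD over markers and standard error of the list's median). This criterion replaced an earlier one after the values were seen. The earlier one asked for marker medians below a fixed bound by more than their standard error. As its whole cause 1 library or a length trend is also argued against, since the list still passed and the groups' mean list scores still differed by at least 0.29 (SD between libraries 0.07) without any 1 library and by 0.35 (SD 0.10) with the length trend removed, each over 2 times that SD. As a part both stay open: the median was 0.31 ± 0.16 with the length trend removed and at least 0.34 ± 0.17 with any 1 library left out, above the 0.3 set in advance by less than the standard error, a margin added after the values were seen. A hypothesis that remains, not tested here, is a stronger glucocorticoid response in the baicalin mice, which may also differ through time of day or handling at collection, neither recorded in the labels used here, though other targets of the receptor in the list did not pass (Tsc22d3 -0.01, Klf9 0.06, Sgk1 0.22, Per1 -0.17).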
